A study of Mus musculus with 6 samples.

How the data were processed

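Single-ended RNA sequencing was done on 6 libraries, 3 control and 3 Rel-deleted, of mouse splenic B cells cultured for 24 h with antibodies against CD40 and IgM. Per the labels' protocols, B cells of 12-week-old mice were purified by magnetic separation, RNA was isolated after culture, and poly-A selected libraries were read on a HiSeq2000. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.4, Cufflinks 2.0.2 and the genome build mm9. The annotation, the counting tool, the use of strand and the treatment of reads that map to several places are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes have uncertain counts.

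The deposited table holds raw read counts per gene name, in 1 column per library, as judged from the deposited values, which are whole numbers that sum to a different total in each library. It was assigned to groups by the column names, which match the sample titles. No column of values was left unused. Of 23284 rows, 7194 were 0 in all libraries. Names in the table are in capitals. They were matched to mouse symbols in an annotation of GRCm38.p6, 21061 by symbol and 1966 by an older symbol, and 35 were ambiguous and 222 had no match. The table includes 25 names that a spreadsheet had turned into dates, which kept the name in the table. The annotation differs from the build of the table and was used only for names, chromosomes and the order of neighbouring genes. No row was blank or a total. The row of the 45S ribosomal RNA precursor took 0.739%, 1.48% and 1.07% of the counts in control replicates 1 to 3 and 0.829%, 0.788% and 1.26% in Rel-deleted replicates 1 to 3.

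The analysis had been planned for FPKM, because the notes name Cufflinks. As the table holds counts, the count test that had been written down for that case was used. Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on genotype alone, after filterByExpr at its default minimum count of 10 and minimum total of 15 and with TMM normalization factors. P-values were adjusted by the Benjamini-Hochberg method over 11670 tested genes with a threshold of 0.05. The SE of a log2 fold change was computed as its absolute value divided by the square root of the quasi-likelihood F statistic. CPM values use library sizes, summed over the tested genes, multiplied by TMM factors. The common biological coefficient of variation was 0.0516.

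Gene lists, 45 in all, were written before the data were examined, as were the tests, the rule for named genes and the alternative settings named as planned. No member of the list of mitochondrially encoded genes is in the table, which leaves 44. Lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, with camera with an estimated correlation and with fry, each adjusted over the lists. The named genes were the 5 NF-κB subunits, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap, and up to 4 members with the smallest p from each list, or 2 where none passed. Predicted genes, immunoglobulin variable segments and short RNA hosts were left out of the 12 largest changes. The rule gave 171 genes, of which the text describes a part. It ranked changes by log2(FPKM + 1), and log2(CPM + 1) took its place after a first run of the same edgeR test had been seen. Genes outside the rule are named as such in the text.

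Replicate libraries were compared before they were averaged. All pairs within a group differed by more than sampling noise, with a chi-square of 4.11 to 10.9 per degree of freedom over the tested genes, so no library appears to be deposited again under another name. The first principal component of log2 CPM held 71.4% of the variance and separated the groups.

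The gene test was checked on simulated counts drawn from the means, dispersions and library sizes of these libraries, with 200 changed genes. Over the 11609 genes tested there, it recovered 24 of 49 genes changed by 1.2-fold, 45 of 50 changed by 1.5-fold, 47 of 49 changed by 2-fold and 50 of 50 changed by 4-fold, with 11 false calls. For lists, over 11606 genes, camera called 5 of 5 shifted lists with either correlation, and 1 of 15 unshifted lists with the preset and 0 of 15 with the estimated correlation. The simulated genes varied independently and the simulated lists were random. In the real lists the estimated correlation was, for example, 0.228 for glycolysis and 0.235 for oxidative phosphorylation. The check therefore does not cover false calls of the preset in lists with correlated members.

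The alternatives planned before the data were examined were no filter on low counts, median-ratio scaling, quantile normalization, a fit without an abundance trend, a robust fit, sample quality weights, a replicate block, DESeq2 1.42.0 and the omission of each library in turn. Pseudocounts do not enter the count test. They were tried with limma on log2(CPM + 1), log2(CPM + 0.1) and log2(CPM + 5), which was chosen after seeing the data, as were a minimum mean of 5 CPM in place of the planned FPKM minimum, library totals without TMM factors, removal of the 45S row and a test against a fold of 1.5.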

Results

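RNA was sequenced from B cells that had been purified from mouse spleen with magnetic beads and cultured for 24 h with antibodies against CD40 and IgM, which engage the co-stimulatory receptor CD40 and the B cell receptor. The 3 control libraries came from 12-week-old mice that carried Cre recombinase in the Cd19 locus. The 3 Rel-deleted libraries came from littermates that carried the same Cre and floxed alleles of Rel, which encodes the NF-κB subunit c-Rel. The deposited table gave whole-number read counts for 23284 gene names. Total counts were 20076821, 22019509 and 18465719 in control replicates 1 to 3 and 20449720, 19634661 and 19572636 in Rel-deleted replicates 1 to 3. Normalised counts are given as CPM, counts scaled to a common library size, as mean ± SD over the 3 libraries of a group. Log2 fold changes are Rel-deleted over control, with standard errors (SE) and adjusted p-values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

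The comparison addresses which transcripts of activated B cells differ when Rel is deleted in the B lineage. Rel itself fell from 602 ± 42.4 CPM in control libraries to 49.2 ± 4.16 CPM in Rel-deleted libraries, which is 8.17% of the control mean (n = 3 per group, log2 fold change −3.61, SE 0.07, edgeR adjusted p = 3.64e-17). Its raw counts lay between 11164 and 13400 in the control libraries and between 897 and 1070 in the Rel-deleted libraries. An exact two-sided permutation test of the Rel level gave p = 0.1, the smallest value that 3 libraries against 3 allow. The remaining counts could not be assigned to exons, so it was not possible to tell transcripts of an undeleted allele from transcripts that lack the floxed part.

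Among the other NF-κB subunits, Relb rose from 146 ± 7.66 to 235 ± 13.6 CPM (log2 fold change 0.69, SE 0.06, edgeR adjusted p = 1.25e-08) and Nfkb1 rose by a log2 fold change of 0.28 (SE 0.05, edgeR adjusted p = 0.000214, n = 3 per group). Nfkb2 stood at 655 ± 16.8 CPM in control and 657 ± 63.3 CPM in Rel-deleted libraries, a difference smaller than the spread between replicates (edgeR adjusted p = 0.97). Rela rose by 0.16 (SE 0.06, edgeR adjusted p = 0.0257), but this call was lost without control replicate 2 (adjusted p = 0.122), without control replicate 3 (0.0832), without Rel-deleted replicate 1 (0.122) and without Rel-deleted replicate 3 (0.0846). Of the 5 subunit genes, 3 rose and 1, Rel, fell, with the same counts adjusted over the list alone. The gene set test camera ranked this list as lower (adjusted p = 0.0162 with the preset correlation, adjusted p = 0.241 with an estimated correlation), while its median log2 fold change was 0.16 and its mean, which includes Rel, was −0.50. Of 16 tested feedback regulators and targets of NF-κB signalling, 9 rose and 2 fell, and the counts were the same adjusted over the list alone. They included Traf3, an adaptor that restrains the non-canonical NF-κB pathway (log2 fold change 0.88), Tnip1 (0.60), the deubiquitinase gene Cyld (0.45) and Bcl3 (0.84). The list was higher by camera (adjusted p = 0.00119), with adjusted p = 0.0955 with an estimated correlation.

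Of the 11670 genes with enough counts to be tested, 2686 rose and 2741 fell in Rel-deleted libraries, together 5427 genes or 46.5% of those tested. TMM scaling places the typical gene near no change, and the median log2 fold change was 0.005. Rises and falls are therefore relative to the other transcripts of a library. No measure of RNA per cell was used, so changes per cell are not known. At least a 2-fold change was estimated for 141 of the genes that rose and for 348 of the genes that fell. The largest rises on the log2(CPM + 1) scale were those of Sspo, which encodes the large extracellular protein SCO-spondin (10.3 ± 0.406 to 111 ± 6.01 CPM), Hspg2, which encodes the basement membrane proteoglycan perlecan (log2 fold change 2.66), Zfp467 (2.65), Serpina3g (2.57), Crisp3 (2.23), Icosl, the gene of the ligand of the T cell co-stimulator ICOS (2.25), and Ltb, the gene of lymphotoxin β (2.10). Il18r1 (2.34), Eif2s3y (2.06), Sema3b (2.46), Itgb3 (2.02) and Hspb1 (2.32) completed the 12 largest rises. Sspo and Zfp467 are neighbours in the GRCm38.p6 annotation, and Serpina3g belongs to a family of near-identical genes, so reads of these genes may have been shared with a neighbour or a copy. The largest falls after Rel were those of Cdk5r1, which encodes an activator of the kinase CDK5 (78.5 ± 8.00 to 9.74 ± 1.72 CPM, log2 fold change −3.01), the chemokine gene Ccl22 (56.2 ± 3.98 to 8.07 ± 0.935 CPM, −2.80) and the fatty acid desaturase gene Fads2 (−3.04). Lrrc32, which encodes the TGF-β anchoring protein GARP, had 309 counts over the control libraries and 8 over the Rel-deleted libraries, with 1 to 5 in each. Scaled to library size, the ratio was 38.5, with an exact 95% interval of 19.3 to 90.0 that covers counting error only. With so few counts the ratio depends strongly on single libraries. The phosphatase gene Dusp14 (−3.55), Bcl2l1 (−2.28), Fam46c (−2.32), the receptor tyrosine kinase gene Axl (−2.13), Tnfsf9 (−2.44), Apold1 (−2.61) and Rgs9bp (−2.56) completed the 12 largest falls.

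**Figure D1:**
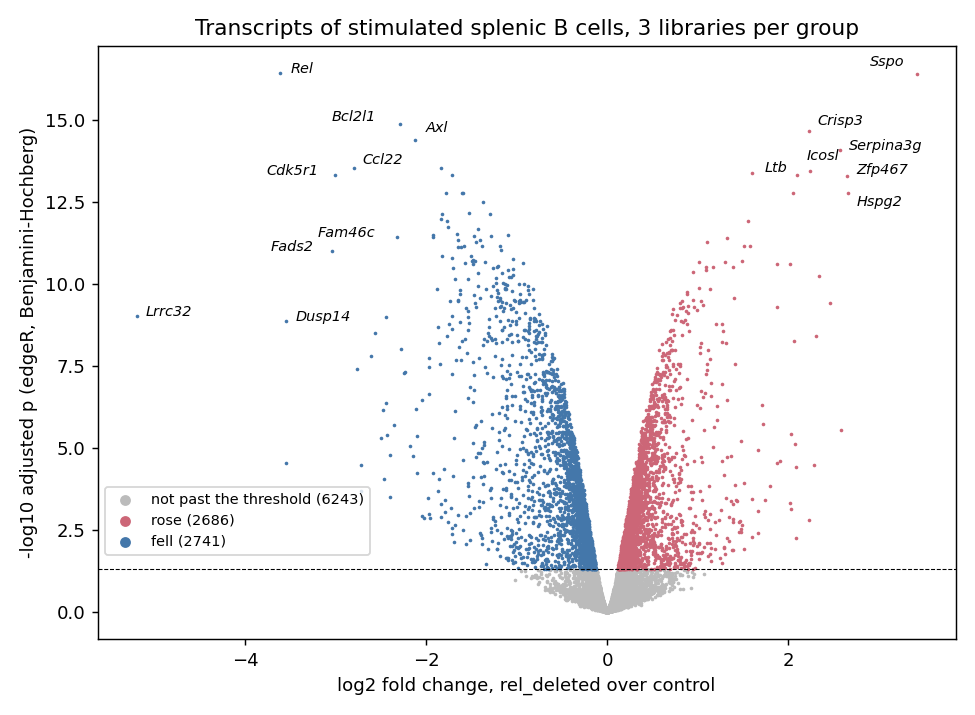
Log2 fold change of each tested gene in Rel-deleted over control libraries (horizontal axis) against −log10 of its adjusted p from edgeR (vertical axis), with 1 point per gene and the dashed line at an adjusted p of 0.05. Of 11670 genes, 2686 rose (red), 2741 fell (blue) and 6243 did not pass the threshold (grey), and Rel lies at −3.61 with the smallest adjusted p.

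The 3 values of a group lay wholly apart from the 3 values of the other group for 6316 of the 11670 tested genes, which is 54.1%. Chance gives 10% for any 1 gene. The genes share the same 6 libraries and are not independent, so any difference between the groups can separate many genes at once. Most changes were small: 4166 of the 5427 called genes changed by less than 1.5-fold, and a test against a fold of 1.5, added after seeing the data, called 523 genes, of which 133 rose and 390 fell. Markers of sex differed with genotype. Xist, the long RNA made from the inactive X chromosome of female cells, fell from 1711 ± 51.9 to 497 ± 44.6 CPM (log2 fold change −1.78, SE 0.06, edgeR adjusted p = 1.67e-13). Ddx3y rose from 46.5 ± 4.10 to 139 ± 14.1 CPM (1.58), Kdm5d from 20.5 ± 0.565 to 60.3 ± 2.37 CPM (1.56) and Eif2s3y from 22.4 ± 1.97 to 93.1 ± 7.78 CPM (2.06), and all 4 Y-linked genes of the list rose. All 6 libraries held both kinds of transcript, with at least 94.5 CPM of the summed Y-linked genes and at least 460 CPM of Xist. The sex-linked list was higher by camera (adjusted p = 2.51e-07), with adjusted p = 0.126 with an estimated correlation, and 4 members rose and 1 fell also adjusted over the list alone. Every gene group described for this comparison was measured between the same libraries, which differed in Xist and Y-linked counts as well as in Rel. The labels do not say that the 3 libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

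**Figure D2:**
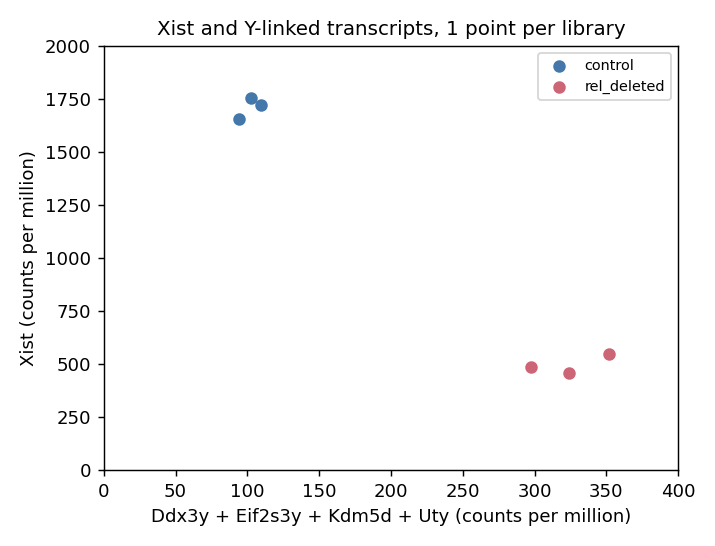
Xist (vertical axis, CPM) against the sum of Ddx3y, Eif2s3y, Kdm5d and Uty (horizontal axis, CPM), with 1 point per library. The 3 control libraries lie between 1655 and 1757 for Xist and between 94.5 and 109 for the Y-linked sum, and the 3 Rel-deleted libraries between 460 and 547 and between 298 and 352.

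Genes that control survival changed in both directions. Bcl2l1, which encodes the anti-apoptotic protein BCL-XL, fell from 169 ± 5.67 to 34.8 ± 1.55 CPM (log2 fold change −2.28, SE 0.06, edgeR adjusted p = 1.34e-15). The anti-apoptotic genes Bcl2a1d (−1.30) and Bcl2a1b (−0.71) also fell, whereas Bcl2 rose from 92.1 ± 4.92 to 151 ± 8.13 CPM (0.71). The Bcl2a1 genes are near-identical copies, and the counts of each are uncertain. In total 2 of 7 pro-survival members rose and 4 fell, or 5 fell adjusted over the list alone, and the list was lower by camera (adjusted p = 1.69e-05), with adjusted p = 0.0698 with an estimated correlation. Among 8 tested pro-apoptotic members, 3 rose and 2 fell, or 3 fell adjusted over the list alone. Bmf rose from 45.5 ± 3.08 to 102 ± 5.09 CPM (1.17), Bcl2l11, which encodes BIM, from 184 ± 13.8 to 337 ± 14.4 CPM (0.87) and Bbc3, which encodes PUMA, by 0.64, while Bak1 fell by 0.29. This list was higher by camera (adjusted p = 0.0459) although its median log2 fold change was −0.11 (mean 0.24), and the call was lost with an estimated correlation (adjusted p = 0.277), with no filter on low counts (0.230), with a mean of at least 5 CPM (0.0596) and without control replicate 2 (0.0629), control replicate 3 (0.0766), Rel-deleted replicate 1 (0.0513) or Rel-deleted replicate 3 (0.0719).

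**Figure D3:**
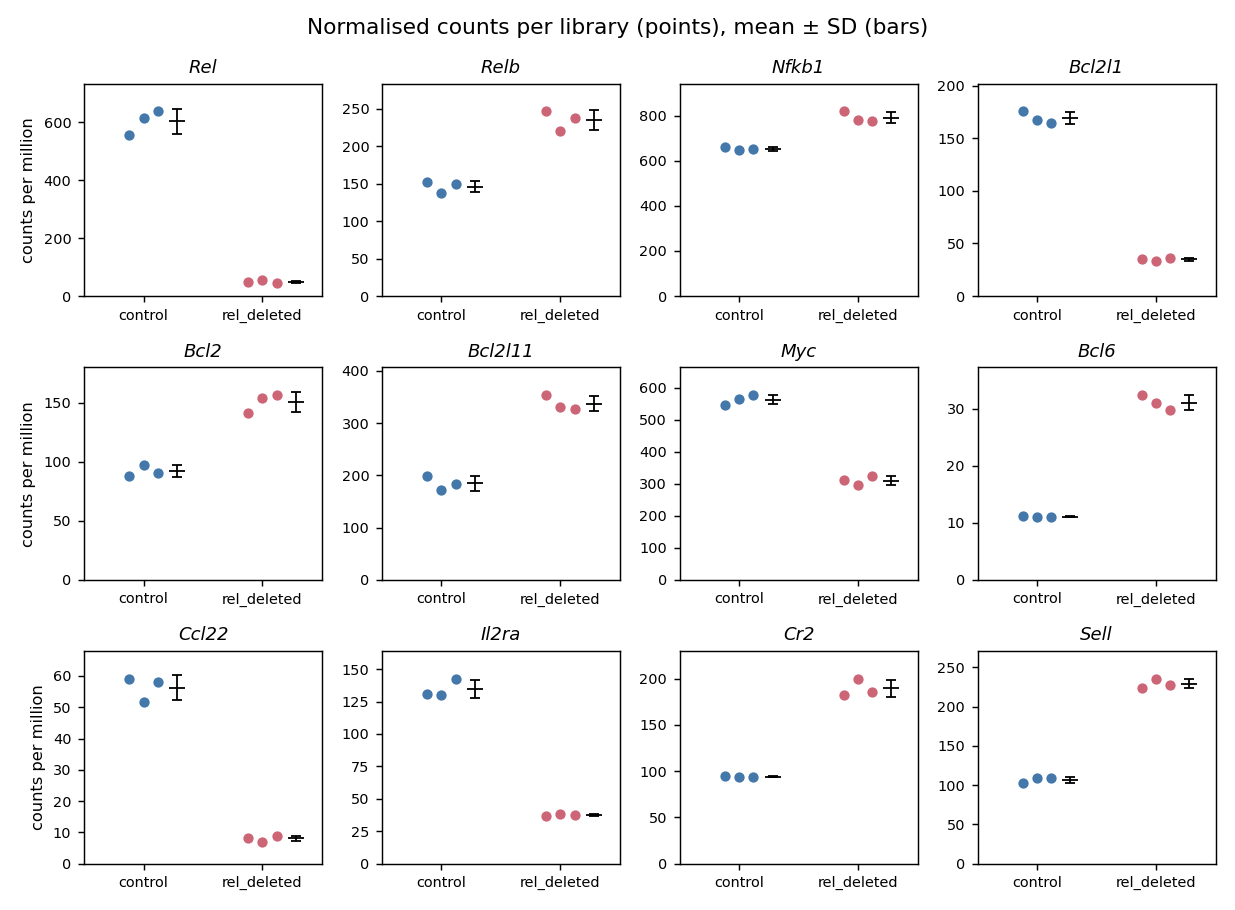
Normalised counts (vertical axis, CPM) of 12 genes in the 3 control (blue) and 3 Rel-deleted (red) libraries, with the mean ± SD beside each group. Rel falls from 602 to 49.2 and Bcl2l1 from 169 to 34.8 CPM, and in each panel the 3 values of a group lie apart from those of the other group.

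Transcripts of activation-associated surface molecules and of cytokines also moved both ways. Il2ra, which encodes the α chain of the interleukin 2 receptor, fell from 135 ± 6.74 to 37.6 ± 0.985 CPM (log2 fold change −1.84) and Tnfsf9, the gene of the ligand of 4-1BB, from 13.1 ± 1.88 to 2.43 ± 0.765 CPM. In contrast Icosl rose from 13.7 ± 1.22 to 64.7 ± 0.428 CPM, Cd40 by 0.96 and Tnfrsf9, which encodes 4-1BB, by 1.88. Of 23 tested surface genes, 4 rose and 10 fell, or 5 rose adjusted over the list alone, and camera made no call (adjusted p = 0.489). Of 16 tested cytokine and chemokine genes, 3 rose and 5 fell, with the same counts adjusted over the list alone, and camera made no call (adjusted p = 0.489). Ltb rose from 32.9 ± 3.99 to 142 ± 4.05 CPM, and the chemokine genes Ccl3 (−1.20) and Ccl4 (−0.80) fell together with Ccl22. Immediate early and heat shock genes fell, 12 of 18 with none rising, including Junb (−0.87), Fos (−0.90), Egr1 (−0.48) and Hsp90aa1 (−0.42). Their counts were the same adjusted over the list alone, and the list was lower by camera (adjusted p = 0.000631), with adjusted p = 0.214 with an estimated correlation. This list had been written as a check of sample quality, so its fall cannot be assigned to Rel alone.

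Cell cycle transcripts fell. All 34 mitosis genes fell, with a median log2 fold change of −1.44. Mki67, the proliferation marker Ki-67, went from 270.0 ± 12.0 to 88.5 ± 6.15 CPM (log2 fold change −1.61, SE 0.06, edgeR adjusted p = 1.67e-13), and Top2a (−1.38), the mitotic kinase gene Cdk1 (−1.83) and the separase gene Espl1 (−1.76) fell as well. All 38 DNA replication genes fell, with a median of −0.73, among them Mcm10 (−1.41), Cdc45 (−1.26) and the DNA ligase gene Lig1 (−1.10). Of 25 genes of the G1 to S phase transition, 16 fell and 3 rose, with falls of Ccna2 (−1.83), E2f8 (−1.47) and E2f1 (−1.14). Counts adjusted over the list alone were the same for these lists. The calls held by camera with the preset correlation (adjusted p = 1.15e-59 for mitosis, 6.91e-47 for DNA replication and 1.03e-07 for the G1 to S list) and with an estimated correlation (adjusted p = 0.00192, 0.0195 and 0.0470).

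Genes of nucleotide and lipid synthesis were lower. Of 25 nucleotide synthesis genes 22 fell and none rose, or 23 fell adjusted over the list alone. They included the ribonucleotide reductase genes Rrm2 (111 ± 2.15 to 38.5 ± 3.05 CPM, log2 fold change −1.53) and Rrm1 (−0.93), the thymidylate synthase gene Tyms (−1.45) and Dhfr (−1.16). The list was lower by camera with the preset (adjusted p = 6.69e-16) and with an estimated correlation (adjusted p = 0.0159). Of 22 cholesterol synthesis genes 18 fell and none rose, or 19 fell adjusted over the list alone, including Lss (−0.72), Fdps (−0.66), Sc5d (−0.53) and Mvd (−0.54). This list too was lower by camera with the preset (adjusted p = 2.51e-07) and with an estimated correlation (adjusted p = 0.0470). Of 15 fatty acid synthesis genes 12 fell and none rose, also adjusted over the list alone. Next to Fads2, the desaturase genes Fads1 (−1.18), Scd2 (−0.82) and Scd1 (−0.76) fell (camera adjusted p = 1.03e-07, and adjusted p = 0.0999 with an estimated correlation).

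Among 20 glycolysis genes 19 fell and 1 rose, also adjusted over the list alone, with falls of the hexokinase gene Hk2 (log2 fold change −0.90), the glucose transporter gene Slc2a1 (−0.97), Tpi1 (−1.01) and Pfkl (−0.64). The list was lower by camera (adjusted p = 8.28e-12), with adjusted p = 0.101 with an estimated correlation. Of 21 genes of the tricarboxylic acid cycle 14 fell and 1 rose, also adjusted over the list alone, with small changes such as Sdhd (−0.32) and Idh3a (−0.32) (camera adjusted p = 0.0294, and adjusted p = 0.241 with an estimated correlation). Of 42 genes of oxidative phosphorylation 30 fell and none rose, or 36 fell adjusted over the list alone, for example Atp5b (−0.41) and Cyc1 (−0.36) (camera adjusted p = 0.000527, and adjusted p = 0.391 with an estimated correlation). Of 12 genes of serine and one-carbon metabolism 10 fell and none rose, also adjusted over the list alone, including Psat1 (−0.79), Shmt1 (−0.72) and Mthfd2 (−0.67) (camera adjusted p = 1.71e-06, and adjusted p = 0.0999 with an estimated correlation). In the list for the response of the stress-responsive factor ATF4, 11 of 16 genes fell and none rose, or 13 fell adjusted over the list alone, including Asns (−1.11) and Chac1 (−1.97) (camera adjusted p = 0.00139, and adjusted p = 0.236 with an estimated correlation). The list holds Atf4 itself, which lies outside the rule for named genes and also fell (−0.31). Of 12 amino acid transporters 2 rose and 6 fell, also adjusted over the list alone, including Slc3a2 (−0.48) and Slc7a5 (−0.42), without a call by camera (adjusted p = 0.219).

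Ribosome biogenesis genes fell for 33 of 39 members and none rose, also adjusted over the list alone, with a median log2 fold change of −0.28 and examples Nolc1 (−0.49), Nop16 (−0.46), Nip7 (−0.47) and Nop56 (−0.41). The list was lower by camera (adjusted p = 2.64e-07), with adjusted p = 0.0944 with an estimated correlation. Of 20 genes in the list for translation initiation 14 fell and none rose, also adjusted over the list alone, including Eif1a (−0.41) and Eif5a (−0.42) (camera adjusted p = 0.000757, and adjusted p = 0.185 with an estimated correlation). The list is broader than its name, as it holds Eef1e1 (−0.52), which does not encode an initiation factor. Of 38 ribosomal protein genes 2 rose and 5 fell, or 2 fell and none rose adjusted over the list alone, without a call by camera (adjusted p = 0.489). Ribosomal protein genes, Tpi1 and other metabolic genes have many processed copies in the genome, and their counts are uncertain. In this table Gapdh had 166 to 433 counts per library, Eno1 0 to 5 and Hmgcs1 0 in all libraries, 3 metabolic genes picked after their values were seen.

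Most genes in the lists for resting and for marginal zone B cells were higher. Of 21 genes of naive or quiescent B cells 16 rose and 1 fell, also adjusted over the list alone. Sell, which encodes L-selectin, rose from 107 ± 3.97 to 229 ± 5.67 CPM (log2 fold change 1.10), S1pr1 by 1.39, Cd55 by 1.09 and Txnip by 0.71. The list was higher by camera with the preset (adjusted p = 1.78e-09) and with an estimated correlation (adjusted p = 0.0470). Of 14 marginal zone genes 8 rose and 4 fell, or 9 rose adjusted over the list alone. Cr2, which encodes complement receptor CD21, rose from 93.9 ± 0.600 to 189.5 ± 8.97 CPM, and Plac8 (0.73) and Ahnak (0.81) rose, while Myof (−0.84) fell (camera adjusted p = 0.00504, and adjusted p = 0.147 with an estimated correlation). The other falls in the marginal zone list were those of Mzb1, named 2010001M09Rik here (−0.28), and of S1pr3 (−0.29) and Cd9 (−0.19), which lie outside the rule for named genes. Of 15 B cell identity genes 9 rose and 2 fell, also adjusted over the list alone, including Fcrla (0.61), Fcer2a, which encodes CD23 (0.52), and Cd22 (0.48) (camera adjusted p = 0.00139, and adjusted p = 0.163 with an estimated correlation). Of 24 genes of B cell receptor signalling 15 rose and 3 fell, or 4 fell adjusted over the list alone, with a rise of Bcl10 (0.55) and a fall of Malt1 (−0.66), which encode partners in the same signalling complex (camera adjusted p = 0.00296, and adjusted p = 0.241 with an estimated correlation). Of 10 genes of MHC class II presentation 8 rose and none fell, also adjusted over the list alone, including H2-Ob (0.74), H2-Oa (0.48), Ciita (0.31) and Cd74 (0.44) (camera adjusted p = 0.00136, and adjusted p = 0.236 with an estimated correlation).

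Regulators of B cell differentiation split by gene. All 19 tested germinal centre genes changed, 9 up and 10 down, also adjusted over the list alone. Bcl6, the transcriptional repressor required for germinal centres, rose from 11.1 ± 0.0737 to 31.1 ± 1.28 CPM (log2 fold change 1.49, SE 0.08, edgeR adjusted p = 2.02e-11) and Id3 rose by 0.90, whereas Myc fell from 563 ± 14.9 to 310 ± 14.2 CPM (−0.86) and Ezh2 fell by 0.93. Camera made no call for this list (adjusted p = 0.967). Of 15 plasma cell genes 4 rose and 5 fell, also adjusted over the list alone, again without a call by camera (adjusted p = 0.856). Prdm1, which encodes BLIMP-1, rose from 3.76 ± 0.135 to 6.31 ± 0.700 CPM (0.75), and Irf4 (−0.30) and the J chain gene Igj (−0.26) fell. Of 24 transcription factors of the B lineage 15 rose and 6 fell, or 16 rose adjusted over the list alone, with a rise of Ikzf3 (0.65) next to those of Bcl6 and Id3 (camera adjusted p = 0.0120, and adjusted p = 0.316 with an estimated correlation).

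**Figure D4:**
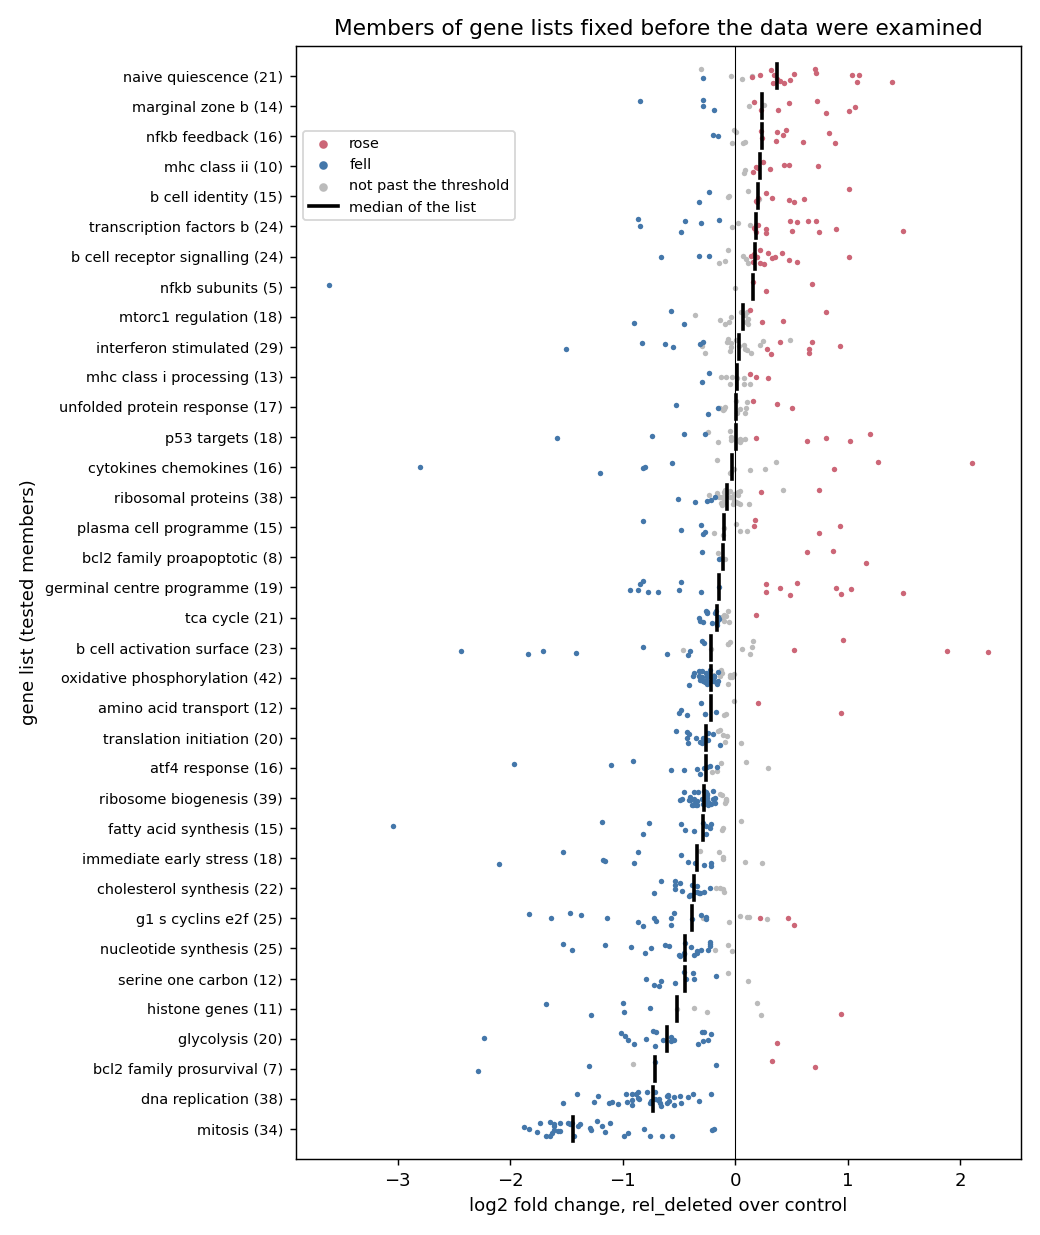
Log2 fold change, Rel-deleted over control (horizontal axis), of the tested members of the gene lists other than those for other cell types and for sex (vertical axis, number of tested members in brackets), with 1 point per gene and a black line at the median of the list. Points are red for genes that rose, blue for genes that fell and grey for genes that did not pass the threshold, and the lowest median shown is that of mitosis at −1.44.

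Of the genes in the lists for other cell types, 68 had too few counts to be tested, with at most 15 counts in any library. Among these, 11 had 0 counts in all libraries, including the globin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2, which have near-identical copies. Because Hmgcs1 was also at 0 and Eno1 at 0 to 5 counts, a 0 in this table does not show that a transcript was absent. For 6 of the 68 genes all Rel-deleted libraries lay above all control libraries and for 0 they lay below. Without ties, chance gives 10% of genes for both directions together, and so less for 1 direction. The 11 genes at 0 in all libraries cannot lie apart, which lowers the chance share further. The 6 genes were Icos (0 to 1 counts in control and 6 to 13 in Rel-deleted libraries), Cd4 (1 to 3 and 5 to 6), Cd14 (0 to 3 and 5 to 6), Csf3r (1 to 5 and 6 to 9), Cx3cr1 (2 and 3 to 8) and Klre1 (0 and 1). They were listed after their values were seen and not tested for a difference. Some tested members, such as Ctss and Mpeg1, are also made by B cells. Of 9 tested T cell genes 3 rose and 1 fell, of which Cd28, Cd6 and Tcf7 lost their calls with DESeq2 (adjusted p = 0.0708, 0.0949 and 0.0991), with Lck at 277 ± 10.6 and 327 ± 14.8 CPM (log2 fold change 0.24). Of 3 tested natural killer cell genes 1 rose and 1 fell, or 2 rose adjusted over the list alone, with Nkg7 at 3.68 ± 0.436 and 0.533 ± 0.157 CPM (−2.77) and Il2rb at 0.83. Of 12 tested macrophage and monocyte genes 5 rose and 3 fell, or 6 rose adjusted over the list alone, with a rise of Emr1 (32.5 ± 1.04 to 53.9 ± 3.20 CPM, 0.73) and of Ctss (0.32) and falls of Mpeg1 (−0.43) and Sirpa (−0.45). Of 7 tested dendritic cell genes 2 fell, of 4 erythroid and platelet genes 1, Car2, fell (−1.12), of 2 stromal and endothelial genes 1, Pecam1, rose (0.42), and of 2 neutrophil genes 1, S100a9, passed (0.924 ± 0.158 and 0.533 ± 0.0290 CPM, edgeR adjusted p = 0.0420) and lost its call with DESeq2 (adjusted p = 0.158) and without each library except control replicate 1 (0.0673 to 0.167). Except for the natural killer and macrophage lists these counts were the same adjusted over the list alone. Camera called none of these 7 lists (adjusted p between 0.461 and 0.899 with the preset correlation).

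Of 44 testable lists, camera with the preset correlation called 25, of which 9 were higher and 16 lower. The lower lists include that of the NF-κB subunits, which holds the deleted gene Rel. The higher lists include that of the sex-linked genes. With an estimated correlation 6 calls held, those for mitosis, DNA replication, nucleotide synthesis, naive and quiescent B cells, cholesterol synthesis and the G1 to S transition. Some lists share members, such as Rrm2 in the lists for nucleotide synthesis and DNA replication. The calls are therefore not independent results.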

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

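The test against a fold of 1.5, the limma tests, the minimum of 5 CPM, library totals alone and the fit without the 45S row were chosen after seeing the data, the other alternatives before. Rel fell past the threshold under every alternative, and no named gene or list changed direction past the threshold. The count of changed genes, 5427 in edgeR, lay between 4581 and 5179 with each library left out in turn, and was 4898 with DESeq2, 5629 with no filter on low counts and 5429 with median-ratio scaling. Library totals alone gave 5433 genes, of which 53.1% rose against 49.5% with TMM factors. The test against a fold of 1.5 called 523 genes (133 rose, 390 fell), since it asks for a larger change, and ended the call of 89 of the 171 named genes. Camera with an estimated correlation called 6 lists against 25 with the preset correlation, and fry, which does not compare a list with other genes, called 35. Apart from the fold test, calls of 9 named genes ended under some alternative. These were Rela, S100a9, Ly6d, Cd28, Cd6, Tcf7 and the ribosomal protein genes Rps8, Rps2 and Rpl10a. Ly6d lost its call without control replicate 2 (adjusted p = 0.149), Rel-deleted replicate 1 (0.136) or replicate 2 (0.0548), and with quantile normalization (0.0854). Cd28 lost it without replicate 1 of either group (0.0524 and 0.0525), Cd6 without control replicate 2 (0.0868) or Rel-deleted replicate 3 (0.111), and Tcf7 without control replicates 2 (0.0816) or 3 (0.136) or Rel-deleted replicates 1 (0.161) or 3 (0.0708). Rps2 lost it without replicate 2 of either group (0.147 and 0.0727) and with DESeq2 (0.128), Rpl10a without control replicate 2 (0.0929) or Rel-deleted replicate 1 (0.101), and Rps8 with DESeq2 (0.0593) and in the robust fit (0.158). S100a9 lost it without each library except control replicate 1 (0.0673 to 0.167), with DESeq2 (0.158), with no filter (0.0831) and with limma on log2(CPM + 1), log2(CPM + 0.1) and log2(CPM + 5) (0.0574, 0.0536 and 0.0836). With DESeq2 Cd28 (0.0708), Cd6 (0.0949) and Tcf7 (0.0991) lost theirs too. The cause was not tested for these genes or for the lists.

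No clear pairing of the libraries by replicate number was seen, although 3 libraries per group are too few to exclude it. Deviations from the group means correlated at 0.13, 0.04 and −0.02 between libraries of the same number. Not every library correlated best with its own number, but the value of 0.13 for replicate 1 was the highest of all pairs. With the replicate number as a block, edgeR called 5893 genes, 2913 up and 2980 down, and among named genes the call of S100a9 ended (adjusted p = 0.0547). In the simulated counts, with 200 changed genes, a change of 1.2-fold was recovered for 49.0% of genes. The real comparison called 5427 genes, which makes the adjusted threshold less strict. The simulated share therefore does not give the share of small changes detected in the real comparison.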

Other observations

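Of the tests in this part, the test of genes that escape X inactivation, the count over other splits of the libraries and the test of 2-fold changes near Rel were written before their results were seen, although the rise of Il9r, which lies on the same chromosome as Rel, had been seen. The tests of carry-over, of mice per library and of a shared pool and the share of all changed genes near Rel were chosen after values had been seen.

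Lists with members that moved in opposite directions held some large changes. Of 29 interferon-stimulated genes 7 rose and 6 fell, also adjusted over the list alone, with Ifih1, which encodes the RNA sensor MDA5, lower (log2 fold change −1.50), Ddx58, which encodes the RNA sensor RIG-I, higher (0.66), Stat2 higher (0.66) and Zbp1 lower (−0.62). Of 18 p53 targets 5 rose and 4 fell, also adjusted over the list alone, with rises of Trp53inp1 (1.02) and Gadd45a (10.2 ± 0.895 to 23.6 ± 0.732 CPM) and a fall of Gtse1 (−0.74). Of 18 genes that regulate the growth kinase complex mTORC1 4 rose and 3 fell, also adjusted over the list alone, with rises of Sesn1 (0.80) and Sesn3 (0.42) and a fall of Rragd (−0.90). Of 17 genes of the unfolded protein response 3 rose and 3 fell, also adjusted over the list alone, with rises of Dnajb9 (0.50) and Syvn1 (0.37) and a fall of Sdf2l1 (−0.53). Of 13 genes of MHC class I processing 3 rose, or 2 adjusted over the list alone, and 2 fell either way, the immunoproteasome genes Psmb9 (−0.30) and Psmb8 (−0.23). Of 11 histone genes 1 rose and 5 fell, or 7 fell adjusted over the list alone, among them Hist1h1b (0.810 ± 0.0934 to 0.251 ± 0.134 CPM); poly-A selection captures few histone transcripts, and histone genes share sequence. Camera called none of these 6 lists (adjusted p between 0.187 and 0.967 with the preset correlation). The median log2 fold change, the mean and the direction of the camera test did not all have the same sign for NF-κB subunits, pro-apoptotic genes, germinal centre genes, mTORC1 regulation, the unfolded protein response, T cell, natural killer cell and erythroid lists.

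The neighbours of Sspo in the GRCm38.p6 order, chosen after its rise had been seen, gave log2 fold changes of 2.65 for Zfp467, 0.42 for Krba1 and 0.22 for Zfp746 on one side and of 0.59 for Zfp862 and 0.18 for Lrrc61 on the other, while Repin1 stood at 0.00 (edgeR adjusted p = 0.964).

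Xist fell and 4 Y-linked genes rose in Rel-deleted libraries, and both kinds of transcript lay together in 6 of 6 libraries, which argues against 1 mouse per library unless RNA was carried over between libraries. Carry-over from control libraries as the whole source of Xist in Rel-deleted libraries was argued against, because these held 8.17% of the control level of Rel but 29.1% of that of Xist. If carry-over from Rel-deleted libraries were the whole source of Y-linked transcripts in control libraries, it would add to every gene alike. No gene would then have a control level below 31.5% of its Rel-deleted level, the share of the summed Y-linked genes. Of 11 other genes among the largest rises, 10 lay below this share by over 3 standard errors. The tally follows from the choice of genes with large rises and has no weight as a count. Each such gene, for example Sspo at 9.31%, still argues against carry-over as the whole source. Carry-over from libraries not used here stays open. A mixture of male and female cells with a larger male share in Rel-deleted libraries may account for the shift, at least in part. The 4 genes that escape X inactivation gave a median log2 fold change of −0.13 against 0.04 for other X-linked genes (permutation p = 0.143 over random sets of genes). Eif2s3x stood at −0.67 and Kdm6a at 0.02, so this test decides nothing. The Y-linked sum was 94.5 to 109 CPM in control and 298 to 352 CPM in Rel-deleted libraries. A larger male share predicts this rise together with the fall of Xist. A changed share alone would raise each Y-linked gene by the same fold. The log2 fold change was 2.06 (SE 0.07) for Eif2s3y but 1.56 (SE 0.06) for Kdm5d. These values argue against a changed share as the whole account of the Y-linked rises. Uty lay at 11.5 to 13.7 CPM in control and 26.4 to 35.4 CPM in Rel-deleted libraries. Lower Xist per cell without Rel predicts no rise of Y-linked genes, which argues against it as the whole account of the shift. Lower Xist per cell as a part of the shift and an effect of the sex of the cells on other genes stay open and were not tested.

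The libraries of a group varied little, and a candidate explanation is that they share 1 pool of cells. The within-group SD of the log2 ratio of Xist to the summed Y-linked genes was 0.0910, at percentile 54.3 of random gene pairs, while the groups differed by 3.45, which is what 1 pool per group predicts; separate pools mixed in like proportions would give the same, so this stays a hypothesis. If it holds, differences between these pools other than Rel stay open. Of the 10 splits of the 6 libraries, 1, the real grouping, gave as many changed genes, 5427 in edgeR, against at most 0 in the others (6186 against at most 448 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05.

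The rise of Il9r (log2 fold change 1.60), which is number 59 of the tested genes in order of distance from Rel in GRCm38.p6, raised the question of a stretch of chromosome from another strain around the floxed allele. Of the 100 tested genes nearest Rel, 5% changed by at least 2-fold, namely Il9r, Fignl1, Hmmr, Gm11974 and Myo1g, all named here after their values were seen, and Il9r is the nearest of them. This lies between the median over windows of 100 neighbouring genes, 4%, and the 95th percentile, 8%. Changes of any size were called for 54% of the 100 genes against 46.5% of all tested genes, below the 95th percentile of windows, 55%, and above 91.9% of windows. The explanation cannot be told apart from an effect of Rel by these values, because such a stretch could carry few expression differences.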
